A study of Prunus persica with 39 samples.

How the data were processed

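The study followed gene expression in peach (cultivar Fantasia) fruit with a single-colour oligonucleotide array. Per the labels' protocols, fruits from 8 trees were collected at 12 time points with at least 50 fruits at each, and 6 of these stages were taken to the arrays after a selection on developmental marker genes. Seed and mesocarp, the fleshy part of the fruit, were separated at each stage, and whole flowers were taken at anthesis. Total RNA came from 2 g of tissue by a CTAB method, and Cy3-labelled cRNA was made from 1 µg of RNA. The 39 arrays fall into 13 groups of 3, which the series description calls biological replicates (A, B and C). Groups and letters were read from the sample titles, because the stage text of mesocarp T7 replicates B and C departs from that of replicate A. The labels do not say which trees or fruits went into which replicate.

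The deposited scanner files hold spot intensity. Per the file headers, spots were read with Agilent Feature Extraction 10.7.3.1, which subtracts the background and gives a processed signal, a mean signal and a background median per spot, with flags for spots well above background, saturated or non-uniform. Each array holds 62976 features, of which 61657 are not controls, and they represent 29744 gene models with 1 probe of 60 bases each, spotted 2 times for 27575 models and 3 times for 2169. No spot of a gene model was saturated on any array. The deposited series table holds a second set of intensity values by the authors. How these were scaled is not given in the sources used here. Over gene models, the column medians of that table lie between 179 and 190, and each column's Spearman correlation with the processed signal of its array is at least 0.998, so the values run in the same direction on a linear scale with arrays brought to near-equal medians. It served as an alternative only.

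Gene names could not be attached. The description column of the files names no product, and none of the gene model identifiers matched any of the 26412 genes of the given RefSeq gene table (assembly Prunus_persica_NCBIv2). The 32 lists of genes by product that had been fixed before the data were examined were therefore void and none was tested. Items are given by their gene model identifier as the files print it. There are 29045 distinct probe sequences, and 1100 gene models share their probe sequence with another model, so their signals cannot be separated. None of the gene models named here shares its sequence with another, but close copies of a gene can still bind the same probe.

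Spots flagged as outliers were left out, the log2 values of a gene model's spots were averaged, and each array's 75th percentile of log2 processed signal over non-control spots was subtracted. All log2 values given here were computed this way from the deposited intensity values. Group means were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The seed and mesocarp fits each held 21 arrays, with flower and the 6 stages of the tissue, and the tissue differences came from a fit of 36 arrays as the seed change minus the mesocarp change. A gene model entered a fit when it was well above background on all 3 arrays of at least 1 group. A gene model is said to have changed when its Benjamini-Hochberg adjusted p was under 0.05 and its change was at least 1 on the log2 scale. For the time courses the adjusted p came from an F-test over the 6 stages, with the highest minus the lowest stage mean as the change. Adjusted p-values below are all from these limma fits, and the number of arrays limits their precision. Figures were drawn with matplotlib 3.10.9.

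The rule for named gene models was set before the data were examined. With no descriptions, at most 2 rising and 2 falling identifiers were taken per stage comparison, and 1 of each sign per tissue difference. They were those with the largest log2 change among models that changed, were well above background on every array compared, and whose groups did not overlap. Chance alone keeps the groups of 3 against 3 arrays apart in 10% of gene models. Where a gene model was not well above background in the other tissue, no fold change is given for it there.

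The 6 slides were scanned as 6 scans and do not cross evenly with the groups. Flower lies alone on slide 6, so slide and group cannot be told apart for flower against either tissue. Mesocarp T1 and T3 lie on slide 3 and mesocarp T5, T7 and part of T10 on slide 4, with no group on both, so for mesocarp T3 to T5 slide could enter only as a random block. The same holds for the mesocarp time course and the tissue difference T3 to T5. Mesocarp T5 to T7, mesocarp T1 to T3 and seed T5 to T7 lie each on 1 slide. No pair of arrays was identical.

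Replicate letters were tested for pairing before any fits were compared. Of the 36 same-letter pairs of arrays in compared groups, 11 had deviations from their group means that correlated above 0.1, over a range from -0.16 to 0.47. In seed T5 to T7 all 3 pairs exceeded 0.1, so the letters were taken to pair the arrays there. The main fits hold no term for the letter, also at this step. The pairing enters only with the letter as a block and in splits that part the pairs. In the other 11 comparisons not every pair exceeded 0.1, so the letters were not taken to pair the arrays. Pairing is not excluded there, since at mesocarp T3 to T5 the 3 pairs were at 0.21, 0.20 and 0.06.

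The procedure was tested on simulated arrays with 200 changed gene models. For mesocarp T5 to T7, over 21166 gene models, it found 35% of models changed by 1 on the log2 scale, 87.5% of those changed by 1.5 and 95% of those changed by 3, with 3 unchanged models called. For the tissue difference T5 to T7, over 22054 gene models, the shares were 52.5%, 75% and 82.5%. Apart from the 200 models, the simulated groups had the same means, the same spread per gene model and no slide effect. The shares and the 3 unchanged models called hold only under those conditions.

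Alternatives fixed beforehand were another background correction (normexp, offset 50), quantile normalization, the array median, the deposited series table, no filter or a stricter filter on dim probes, other sets of arrays in the fit, the replicate letter or the slide as a block, other thresholds, and leaving out each replicate. The deposited series table gave values close to those of quantile normalization, so these 2 alternatives are not separate checks of the scaling. At seed T3 to T5, for example, 47.9% of changed models were higher with the table and 47.7% with quantile normalization.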

Results

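Expression was measured in seed and mesocarp at 6 stages of fruit growth and in flowers at anthesis, on 3 arrays per group. The stages were T1 at 41 days after full bloom, in the first exponential growth of the fruit, T3 at 54 days, T5 at 69 days, when the pit hardens, T7 at 83 days, T10 at 111 days, in the second exponential growth, and T11 at 125 days, at the onset of ripening. The seed held almost only endosperm at T1 and T3, endosperm with a growing embryo at T5 and T7, and a mature embryo at T10 and T11. The study asked which genes changed between successive stages of a tissue and whether the change belonged to the tissue or to the stage. Levels are log2 signals relative to the 75th percentile of the array, given as mean ± SD of 3 arrays, and changes are log2 differences ± SE.

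Of the 29744 gene models, 23771 were well above background on at least 1 array, and single arrays detected between 17267 and 20157. Flower arrays detected 19913 ± 219 gene models (SD, n = 3), seed T1 19451 ± 312 and seed T10 17717 ± 297. In mesocarp the number was 19589 ± 283 at T1 and 18043 ± 683 at T11. The 75th percentile of the signal lay between 745 and 4215. All 13 groups detected 14278 gene models on all of their arrays. A further 950 gene models were detected on all 3 arrays of some seed stage and on no mesocarp or flower array, 231 likewise in mesocarp alone and 290 in flower alone. Of the gene models with the prefix ppa, 82.2% were detected on at least 1 array, against 80.1% of those with the prefix ppapd and 42.4% with ppb. Replicates correlated at 0.983 to 0.997 within every group except seed T11, where the lowest r was 0.943 across gene models, which are not independent.

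Most detected gene models varied over development. In seed, 15077 of 22203 gene models (67.9%) changed over the 6 stages, and in mesocarp 13002 of 21166 (61.4%). Among those of seed, 3390 had their highest mean at T1, 3531 at T10 and 2892 at T11, against 1252 at T7. In mesocarp the highest mean fell at T1 for 4125 and at T11 for 3492 gene models, and the stages in between had 1153 to 1538 each. Of the 10263 gene models that changed in both tissues, 2754 had their highest mean at the same stage, where independent lists would give 1951. The stage of the highest mean was taken relative to the 75th percentile only, and no other scaling was run for it. It can depend on that scaling. A level near background shifts with the percentile, which averaged 3040 in seed T1 and 795 in seed T10.

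**Figure D1:**
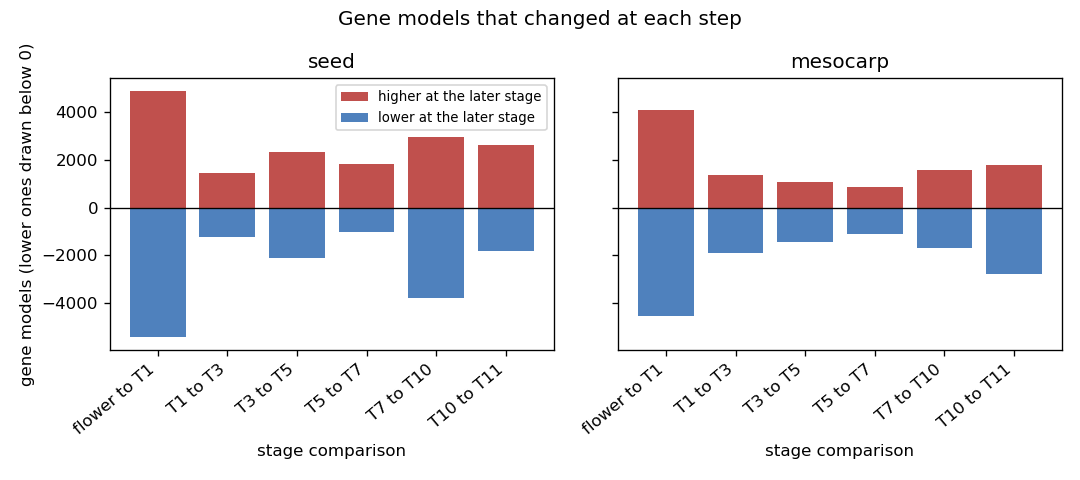
Bars give the number of gene models that were higher (above 0) or lower (below 0) at the later stage of each comparison, on the vertical axis, for seed (left panel) and mesocarp (right panel), with the comparisons along the horizontal axis. Flower against T1 gave the most in both tissues, 10330 in seed and 8639 in mesocarp, and T7 to T10 gave 6758 in seed and 3301 in mesocarp.

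Flower differed from the first fruit stage in 10330 gene models for seed, of which 4898 were higher in seed T1 and 5432 lower. The gene model ppb022512m, whose probe is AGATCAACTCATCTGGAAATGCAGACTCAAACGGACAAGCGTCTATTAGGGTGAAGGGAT, stood at -4.81 ± 0.08 in flower and 5.32 ± 0.28 in seed T1, a change of 10.13 ± 0.39 (adjusted p = 1.3e-12). Among gene models well above background on every array compared, the largest fall was that of ppa022132m, from 4.49 ± 0.07 to -5.86 ± 0.17 (adjusted p = 1.3e-12). In mesocarp T1, 4112 gene models were higher than in flower and 4527 lower. The gene model ppa024769m rose from -4.82 ± 0.04 to 3.04 ± 0.16, and ppa020486m fell from 5.66 ± 0.10 to -4.67 ± 0.06 and also fell by 9.82 in seed. Both tissues shared 2281 gene models above and 3231 below flower, where independent lists would share 808 and 1132, and 629 went opposite ways against 1913. Across genes the changes correlated at 0.67, against 0.50 in simulated groups without any change that share the flower arrays, and their covariance was 3.28 against 0.0109. When the flower arrays were split in 6 ways so that none served both tissues, the tissues shared 2136 to 2322 gene models above and 3061 to 3155 below flower, against 771 to 800 and 1043 to 1097 for independent lists. The correlation was then 0.66 to 0.68, with 1 flower array in 1 of the tissues, assumed to vary like the other groups. Slide and group cannot be told apart here. The share that was higher in seed T1 was 47.4%, and lay above 50% under 6 of 13 alternatives, at 58.6% with quantile normalization, 57.8% with the array median, 58.2% with the deposited series table, 54.1% with the stricter filter on dim probes, 85.6% with control probe scaling and 55.3% with no fold minimum, while the lowest was 38.0% with normexp. In mesocarp T1 the share was 47.6%, and lay above 50% under 6 of 13 alternatives, at 57.5% with quantile normalization, 60.6% with the array median, 57.2% with the deposited series table, 52.7% with the stricter filter on dim probes, 70.4% with control probe scaling and 52.8% with no fold minimum, while the lowest was 41.9% with normexp.

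Between seed T1 and T3, both in the endosperm stage, 1435 gene models rose and 1224 fell. Among models well above background on all 6 arrays, the largest rise was that of ppa018792m, from -5.24 ± 0.41 to 1.63 ± 0.59, a change of 6.88 ± 0.44 (adjusted p = 1.7e-08), and this gene model was not well above background on any mesocarp array of these stages. The rise of ppa004829m was seen in both tissues, by 5.15 ± 0.68 in seed (adjusted p = 3.1e-05). In mesocarp it went from -5.01 ± 0.24 to -0.71 ± 0.20 (adjusted p = 3.0e-12). The difference between the tissues was not called (adjusted p = 0.46), which does not show that the changes are equal. That test uses a spread shared by all groups of the fit. The SD of ppa004829m was 2.27 at seed T11, against 0.12 at seed T1 and 0.24 at seed T3. The gene model ppa021393m fell from 0.79 ± 0.23 to -4.31 ± 0.52 in seed, and fell by 3.12 in mesocarp. For seed T1 to T3 on slide 1, which holds all arrays of T1 and 1 of T3, 2108 gene models changed, with the lone array assumed to vary like the other groups. When scaled to control probes, 8279 changed. The share that was higher was 54.0%, and lay below 50% under 1 of 14 alternatives, at 5.02% with control probe scaling, while the highest was 58.3% with normexp.

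From T3 to T5, as the embryo appeared and the pit hardened, 2324 gene models rose in seed and 2106 fell. The gene model ppa004418m, with the probe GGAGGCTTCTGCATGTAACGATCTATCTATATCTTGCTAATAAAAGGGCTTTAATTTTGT, rose from -5.14 ± 0.81 to 2.75 ± 1.04, by 7.89 ± 0.58 (adjusted p = 2.2e-08), and was not well above background on any mesocarp array of these stages. The fall of ppa013722m was from 4.04 ± 0.09 to -4.17 ± 0.58. The gene model ppa014628m fell by 6.34 in seed. In mesocarp it was at -0.07 ± 0.20 at T3 and not well above background on any T5 array. For seed T3 to T5 on slide 2, which holds 2 arrays of T3 and all of T5, 4320 gene models changed. When scaled to control probes, 9348 changed. Of the changed models, the share that was higher was 52.5%, and lay below 50% under 4 of 14 alternatives, at 47.7% with quantile normalization, 48.0% with the array median, 47.9% with the deposited series table and 10.6% with control probe scaling, while the highest was 58.5% with normexp.

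From T5 to T7, 1810 gene models rose in seed and 1014 fell. The gene model ppa003759m rose from -3.84 ± 1.58 to 5.08 ± 0.18, a change of 8.93 ± 0.63 (adjusted p = 9.8e-08). The rise of ppa008651m was 6.41 ± 0.49 in seed and 1.30 in mesocarp, and the tissues differed (adjusted p = 1.3e-06). The gene model ppa010081m fell from 0.76 ± 0.69 to -4.20 ± 1.17. Both stages lie on 1 slide. Normexp gave 1542 and control probe scaling 1500 for seed T5 to T7. Rising models made up 64.1% of those changed, a share that lay below 50% under 1 of 14 alternatives, at 48.8% with no fold minimum, while the highest was 65.3% with normexp.

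Seed T7 to T10, between the growing and the mature embryo and 28 days apart, had 2965 gene models up and 3793 down. This was the most of the successive seed stages except with control probe scaling, where seed T7 to T10 gave 6022, seed T1 to T3 8279 and seed T3 to T5 9348. The gene model ppa013733m, probe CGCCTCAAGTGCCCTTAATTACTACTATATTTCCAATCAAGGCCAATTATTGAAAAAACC, rose from -4.11 ± 0.38 to 5.93 ± 0.20, a change of 10.04 ± 0.23 (adjusted p = 2.7e-14), and remained at 5.98 ± 0.33 at T11. The gene model ppa006032m rose by 9.07 ± 0.55 in seed, and in mesocarp it was well above background on 1 of 3 T7 arrays and on all T10 arrays. The gene model ppa010163m fell from 3.11 ± 0.19 to -4.37 ± 0.41, while its change in mesocarp was 0.25 (adjusted p = 0.34), and the tissues differed (adjusted p = 1.3e-16). Among changed models the share that was higher was 43.9%, and lay above 50% under 5 of 14 alternatives, at 59.5% with normexp, 65.9% with the array median, 52.0% with no filter on dim probes, 51.2% with the stricter filter on dim probes and 52.2% with no fold minimum, while the lowest was 31.7% with control probe scaling. No slide holds both stages, and for seed T7 to T10 with slide as a block 5364 gene models changed.

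Between seed T10 and T11, 2616 gene models rose and 1813 fell, but T11 replicate C stood apart from A and B. The gene model ppa012449m was between -4.39 and -3.23 on the T10 arrays and at 4.15, 5.26 and -1.12 on T11 replicates A, B and C, a change of 6.42 ± 1.07 (adjusted p = 0.00017). Likewise ppa019992m was at 5.10, 6.29 and -1.55 on these arrays. The SE and adjusted p of ppa012449m rest on a spread shared by all groups of the fit. Its SD was 3.41 at T11 against 0.63 at T10, so they do not measure the disagreement of the T11 arrays. The falls of ppa011560m and ppa013300m were seen on all 3, with ppa011560m going from 0.46 ± 0.26 to -4.25 ± 0.12 (adjusted p = 2.5e-08). For seed T10 to T11 the count was 3287 without T11 replicate B and 5571 without T11 replicate C, and 2766 when only these 6 arrays were fitted. On slide 1 it was 4369, but that rests on 1 array of T11, assumed to vary like the other groups. The later stage was higher in 59.1% of those changed, a share that lay below 50% under 3 of 14 alternatives, at 47.2% with the array median, 43.7% with only these arrays in the fit and 38.7% with no fold minimum, while the highest was 73.5% with control probe scaling.

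In mesocarp, T1 to T3 brought 1366 rises and 1908 falls. The gene model ppa004816m rose from -5.52 ± 0.10 to -1.14 ± 0.27 (adjusted p = 1.7e-12), and rose by 4.96 in seed. The gene model ppa006071m fell from 1.97 ± 0.37 to -3.50 ± 0.39. The gene model ppa014060m fell by 5.67 ± 0.81 on average, with an SD of 2.66 at T3, and in seed it was well above background on all T1 arrays and no T3 array. Both stages lie on 1 slide. The share that was higher was 41.7%, and lay above 50% under 1 of 14 alternatives, at 51.5% with no fold minimum, while the lowest was 28.7% with control probe scaling.

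Mesocarp T3 to T5 had 1064 rises and 1433 falls. The gene model ppa007464m rose from -3.97 ± 0.25 to 1.87 ± 0.13 (adjusted p = 4.8e-11) and also rose in seed, by 4.43. The gene model ppa008769m rose by 5.23 ± 0.71 and was not well above background on any seed array of these stages. The gene model ppa008837m, probe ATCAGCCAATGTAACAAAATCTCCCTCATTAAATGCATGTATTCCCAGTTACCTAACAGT, fell from 0.52 ± 0.06 to -4.99 ± 0.25 (adjusted p = 6.6e-16). The stages lie on different slides with no group on both, and with slide as a random block 1879 gene models changed. Of the changed models, the share that was higher was 42.6%, and lay above 50% under 2 of 14 alternatives, at 53.8% with normexp and 53.4% with the array median, while the lowest was 6.81% with control probe scaling.

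From T5 to T7, 885 gene models rose in mesocarp and 1111 fell. The gene model ppa008837m rose again to 0.38 ± 0.10, by 5.37 ± 0.10 (adjusted p = 1.0e-15), and in seed it rose by 1.63. The gene model ppa006285m fell from 2.47 ± 0.04 to -2.28 ± 0.62, and in seed by 1.89. The gene model ppa005351m fell by 4.64 ± 0.47 in mesocarp, whereas in seed it was well above background on 2 of 3 T5 arrays and all T7 arrays. Both stages lie on 1 slide. Normexp left 992 changed gene models for mesocarp T5 to T7. Rising models made up 44.3% of those changed, a share that lay above 50% under 2 of 14 alternatives, at 51.3% with normexp and 51.2% with the array median, while the lowest was 14.7% with control probe scaling.

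Mesocarp T7 to T10 had 1594 rises and 1707 falls. The gene model ppa006665m rose from -2.11 ± 0.84 to 4.11 ± 0.11 (adjusted p = 4.7e-11) and by 2.71 in seed. The gene model ppa009439m, probe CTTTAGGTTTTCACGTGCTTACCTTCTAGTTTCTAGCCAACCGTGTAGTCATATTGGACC, fell from 4.11 ± 0.07 to -3.47 ± 0.11, a change of -7.58 ± 0.16 (adjusted p = 1.7e-15), against -1.49 in seed, and the tissues differed (adjusted p = 2.7e-13). For mesocarp T7 to T10 on slide 4, with all arrays of T7 and 2 of T10, 3314 gene models changed. Among changed models the share that was higher was 48.3%, and lay above 50% under 2 of 14 alternatives, at 50.4% with no filter on dim probes and 50.97% with slide as a block, while the lowest was 40.4% with control probe scaling.

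At the onset of ripening, T10 to T11, 1793 gene models rose in mesocarp and 2786 fell. This was the most of the successive mesocarp stages except with control probe scaling, where mesocarp T10 to T11 gave 4198 and mesocarp T3 to T5 5723. The gene model ppa005532m rose from -3.83 ± 0.21 to 2.87 ± 0.48 (adjusted p = 1.6e-13), while in seed it was at 4.26 ± 0.15 and 3.83 ± 0.53. The gene model ppa002314m rose by 6.62 ± 0.18 in mesocarp (adjusted p = 1.8e-14), with a change of 0.47 in seed (adjusted p = 0.16). The gene model ppapd-g30896.t1 fell from 5.41 ± 0.42 to -1.48 ± 0.36, and in seed it was well above background on 1 of 3 T10 arrays and on T11 replicates A and B but not C. The gene model ppa009110m fell by 6.70 ± 0.24 in mesocarp. Slide 5 holds 1 array of T10 and all of T11, so a contrast within it rests on a lone T10 array. That array, replicate C, differed from T10 replicates A and B, on slide 4, in more gene models than these did from each other. Slide and array cannot be told apart there. Of the gene models that changed in mesocarp T10 to T11, 39.2% were higher at T11. This share lay above 50% under 1 of 14 alternatives, at 56.9% with control probe scaling. The lowest was 36.5% with no filter on dim probes.

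**Figure D2:**
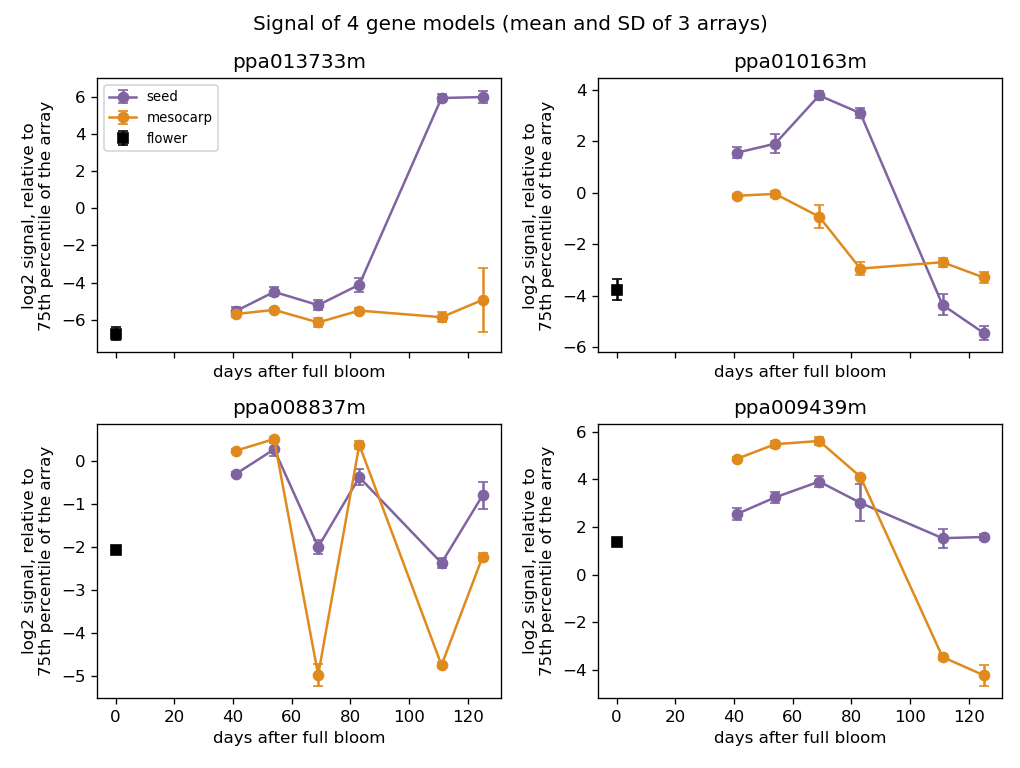
Each panel plots 1 gene model, with days after full bloom on the horizontal axis and log2 signal relative to the 75th percentile of the array on the vertical axis. Points are means and bars SDs of 3 arrays for seed, mesocarp and flower. The gene model ppa013733m is at 5.93 in seed T10 and -5.86 in mesocarp T10, where no array was well above background, and ppa008837m is lower at T5 and T10 than at T7 in both tissues.

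Whether a step belonged to the stage or to the tissue was examined by the overlap between tissues and by the difference of their changes. At T1 to T3 both tissues shared 402 rising and 475 falling gene models, where independent lists would share 74.1 and 88.4, and the changes correlated at 0.39 across gene models. At T3 to T5 the shared numbers were 260 and 459 (87.4 and 125 for independent lists, r = 0.20), and at T5 to T7 they were 227 and 212 (61.5 and 41.9, r = 0.17). At T7 to T10 the shared numbers were 216 and 534 (184 and 272, r = 0.01). At T10 to T11 both tissues shared 484 rises and 449 falls (207 and 192, r = 0.05). Gene models that rose in seed and fell in mesocarp numbered 86, 178, 137, 243 and 521 over the 5 steps, against 107, 122, 76.5, 199 and 325 for independent lists. The reverse numbered 34, 93, 30, 492 and 132, against 61.1, 89.7, 33.7, 250 and 122. No array is shared between the 2 tissues in these comparisons. Between different steps of the 2 tissues the correlation reached 0.20, for seed T1 to T3 with mesocarp T5 to T7. The lowest was -0.17, for seed T10 to T11 with mesocarp T7 to T10. Of the same-step values, only the 0.39 of T1 to T3 stood clearly above that range. Genes are not independent replicates, so the correlations carry no p-value.

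The changes of seed and mesocarp differed in 2906 gene models at T1 to T3, 4632 at T3 to T5, 3327 at T5 to T7, 8243 at T7 to T10 and 6034 at T10 to T11, of 22054 tested. At T1 to T3 the gene model ppa004988m changed by 4.44 in seed and -1.85 in mesocarp. The difference was 6.29 ± 1.47 (adjusted p = 0.0023), and without replicate C it was 5.51 with an adjusted p of 0.059. The shared spread behind these values takes in seed T11, where the SD of ppa004988m was 3.90. At T3 to T5 ppa026283m rose by 5.08 in seed and fell by 2.24 in mesocarp, and ppa009090m fell by 2.33 in seed and rose by 5.18 in mesocarp. At T5 to T7 ppa014189m rose by 4.56 in seed and fell by 1.56 in mesocarp. At T7 to T10 ppa005423m rose by 6.45 in seed and fell by 1.61 in mesocarp, and ppa011029m fell by 3.11 in seed and rose by 5.34 in mesocarp (adjusted p = 3.3e-11). At T10 to T11 ppa013300m fell by 5.01 in seed and rose by 2.33 in mesocarp (adjusted p = 3.2e-06). The count at T5 to T7 was 1751 without replicate A. At T10 to T11, where seed T11 replicate C stood apart, the count was 4517 without replicate B and 7205 without replicate C. At T1 to T3 the share with the higher change in seed was 58.1%, and lay below 50% at 21.8% with control probe scaling. At T3 to T5 the share with the higher change in seed was 54.6%, and lay below 50% at 48.4% with quantile normalization, 43.5% with the array median, 49.0% with the deposited series table, 48.2% with the stricter filter on dim probes and 49.5% with control probe scaling. At T5 to T7 the share with the higher change in seed was 62.4%, and lay below 50% at 45.4% with normexp and 49.2% with no fold minimum. At T7 to T10 the share with the higher change in seed was 46.7%, and lay above 50% at 67.0% with normexp, 64.1% with the array median, 50.6% with no filter on dim probes, 50.4% with the stricter filter on dim probes and 50.5% with no fold minimum. At T10 to T11 the share with the higher change in seed was 57.6%, and lay below 50% at 45.6% with quantile normalization, 40.9% with the array median, 46.5% with the deposited series table, 49.5% with the stricter filter on dim probes and 45.7% with no fold minimum.

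**Figure D3:**
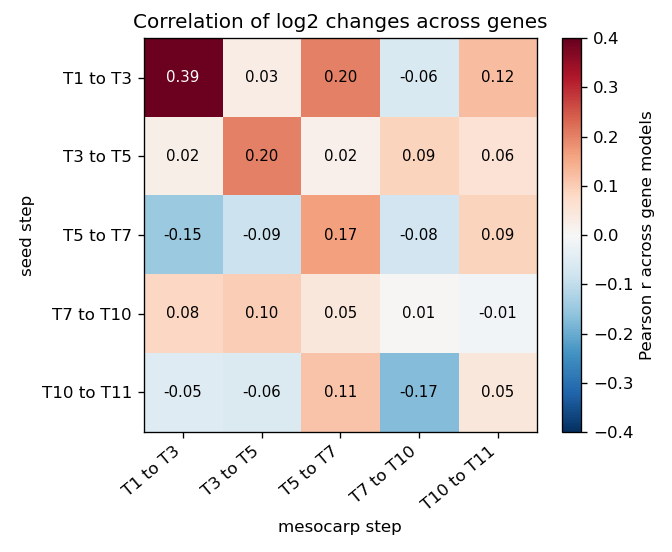
Cells give the Pearson correlation across gene models between the log2 changes of a seed step (rows) and a mesocarp step (columns), with colour from -0.4 to 0.4. The correlation is highest for T1 to T3 in both tissues, at 0.39, and T10 to T11 in seed against T7 to T10 in mesocarp gave -0.17.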

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

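Of the tests in this part, those on slide, on the identity of replicate C and on mesocarp RNA as the whole cause, all on the control probes, and the splits within each tissue or parting the seed pairs were chosen after the values were seen, and the bounds for the tests on mesocarp RNA and on different points of a change were revised once after group values had been seen. The changes of seed and mesocarp differed, by the test of the difference itself, in 2906 gene models at T1 to T3, 4632 at T3 to T5, 3327 at T5 to T7, 8243 at T7 to T10 and 6034 at T10 to T11. The differences (seed minus mesocarp) of the named gene models were 6.29 for ppa004988m and -4.39 for ppa021433m at T1 to T3, 7.32 for ppa026283m and -7.51 for ppa009090m at T3 to T5, 6.12 for ppa014189m and -4.17 for ppa022582m at T5 to T7, 8.05 for ppa005423m and -8.44 for ppa011029m at T7 to T10, and 9.19 for ppa019992m and -7.34 for ppa013300m at T10 to T11. The difference for ppa019992m ranged from 7.11 without replicate B to 12.08 without replicate C, since the seed T11 arrays disagree. In 100 drawn splits of the 12 arrays of each difference, 7, 11, 8, 7 and 10 splits gave as many gene models, with highest other counts of 7707, 9017, 10030, 9331 and 11521. These splits also exchange seed with mesocarp arrays, and the high counts point to that structure of the samples, so they do not measure chance. In 100 splits that exchanged only the stages within each tissue, 8 gave as many at T1 to T3, with a highest other count of 6059. Such splits can keep the stage change of 1 tissue or turn the difference into a sum, so this high number decides nothing about chance. The numbers were 2 of 100 at T3 to T5, 1 at T5 to T7, 1 at T7 to T10 and 2 at T10 to T11. The highest other counts were 6635, 2464, 8073 and 7621. For these 4 steps the share of such splits was under 0.05, which excludes only that neither tissue changed with stage. The splits assume no stage change in either tissue, so they do not test whether the 2 changes differ. Chance as a source of the tissue difference is therefore not excluded by them at any step. The letters pair the seed arrays at T5 to T7, and of the 80 splits that part all 3 seed pairs there, 2 gave as many. The highest other count was 4349, which excludes chance only in the same limited sense.

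For the time courses, 1 of 100 splits, the real one, gave 15077 gene models in seed (highest other 6493) and 1 of 100 gave 13002 in mesocarp (highest other 9001). This excludes a chance assignment of the arrays to the stages of a tissue. It does not exclude a part played by slide, which for the mesocarp time course could not be a fixed block. Comparisons of 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real and highest other counts were 10330 and 0 for flower to seed T1, 2659 and 0, 4430 and 23, 2824 and 528, 6758 and 13, and 4429 and 1158 for the seed steps in order. They were 8639 and 0 for flower to mesocarp T1, and 3274 and 1, 2497 and 0, 1996 and 53, 3301 and 52, and 4579 and 204 for the mesocarp steps. The 10 splits of seed T5 to T7 ignore the letters. Of the 4 that part all seed pairs, the real one gave 2824 and the highest other 0, again too few to test chance.

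Seed T11 replicate C stood further from A and B than any 2 arrays of another group from each other: A and B differed by 1 or more on the log2 scale in 1599 tested gene models, A and C in 3440, and B and C in 4266, although B and C share a slide, 2.67 times as many as A and B, which argues against slide as the cause. Replicate C is also not like a seed T10 array under a wrong label: it differed from the T10 mean in 3163 gene models, 6.36 times the 497 of the most distant T10 array. Mesocarp T11 RNA as the whole cause is argued against by the gene models higher by 1 or more on A than on C. Of these, 44.2% exceeded C, every seed T10 array and every mesocarp T11 array by 1 or more. For B the share was 42.8%. Against all mesocarp stages the shares were 25.4% and 23.1%, and that of B fell short of the bound set for the test. A part played by mesocarp RNA stays open, since of the 200 brightest mesocarp T11 gene models absent from seed T10, 65% were well above background on A, 62.5% on B and 18% on C, at median levels of -5.02, -4.84 and -6.96 relative to mesocarp T11. Also open, as a hypothesis, is that the 3 samples caught seeds at different points of one change, since the change of C from T10 correlated at 0.438 across genes with that of A and 0.473 with that of B, no T10 array being shared, and was smaller (SD 0.874 against 1.52 and 1.61).

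The E1A control probes, which match a control transcript, lay outside the comparisons and were bright on every array, with a lowest array mean of 11.78 on the log2 scale against 4.66 for the highest 95th percentile of the negative controls. The labels do not say whether or how much of this transcript was added. Relative to these probes the 75th percentile was -0.43 ± 0.42 in seed T1 and -2.55 ± 0.23 in seed T10, a difference of 2.12 on the same slide, which argues against slide or scan brightness. The total signal over the E1A signal was 2.91 times higher in seed T1, which argues against a few gene models taking most of the signal as the whole cause. The messenger RNA share of the total RNA and the amount of control transcript cannot be told apart, because 0 control spots of the ERCC and ETG sets were well above background on over 90% of arrays to serve as a second reference.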

How the results depend on the processing

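Scaling to the E1A control probes, 1 gene model per probe sequence, the contrasts within a slide and the split of the flower arrays were chosen after seeing the data. Contrasts within a slide gave the same counts as slide as a block and are counted once. Of 264 counts under the alternatives, 207 were within 1.5 times the main count and 57 were not, and no named gene model reversed. A stricter filter, well above background on all arrays compared, tests fewer gene models and gave 8607 for seed time course, 6715 for flower to seed T1, 2727 for seed T3 to T5, 1546 for seed T5 to T7, 3921 for seed T7 to T10, 2306 for seed T10 to T11, 8458 for mesocarp time course, 1560 for mesocarp T3 to T5, 1255 for mesocarp T5 to T7, 2187 for mesocarp T7 to T10, 2651 for mesocarp T10 to T11, 1526 for tissue difference T1 to T3, 2307 for tissue difference T3 to T5, 1447 for tissue difference T5 to T7, 4503 for tissue difference T7 to T10 and 2953 for tissue difference T10 to T11. With no fold minimum, which admits smaller changes, the counts were 17241 for flower to seed T1, 7702 for seed T1 to T3, 10454 for seed T3 to T5, 6603 for seed T5 to T7, 14330 for seed T7 to T10, 11473 for seed T10 to T11, 19979 for mesocarp time course, 16183 for flower to mesocarp T1, 10179 for mesocarp T1 to T3, 9298 for mesocarp T3 to T5, 7189 for mesocarp T5 to T7, 11073 for mesocarp T7 to T10, 12658 for mesocarp T10 to T11, 5369 for tissue difference T1 to T3, 8069 for tissue difference T3 to T5, 5860 for tissue difference T5 to T7, 13345 for tissue difference T7 to T10 and 10967 for tissue difference T10 to T11. Normexp gave 2905 for seed T3 to T5, 1542 for seed T5 to T7, 4470 for seed T7 to T10, 2455 for seed T10 to T11, 1914 for mesocarp T1 to T3, 1272 for mesocarp T3 to T5, 992 for mesocarp T5 to T7, 1746 for mesocarp T7 to T10, 2602 for mesocarp T10 to T11, 2090 for tissue difference T5 to T7 and 4014 for tissue difference T10 to T11, and the cause was not tested. Scaling to the E1A probes gave 18421 for flower to seed T1, 8279 for seed T1 to T3, 9348 for seed T3 to T5, 1500 for seed T5 to T7, 2826 for seed T10 to T11, 5723 for mesocarp T3 to T5, 1106 for tissue difference T1 to T3, 2032 for tissue difference T3 to T5, 1396 for tissue difference T5 to T7, 4536 for tissue difference T7 to T10 and 2677 for tissue difference T10 to T11, with the median change of all gene models moved by -0.92 to 1.80. This scaling shifts all gene models of an array by the same amount. The median therefore moves with the 75th percentile relative to these probes, which averaged -0.43 in seed T1 and -1.34 in seed T3. Why that level differs between groups is not settled. Fitting only the 6 arrays compared gave 2766 for seed T10 to T11. Leaving out 1 replicate, the tissue difference T5 to T7 ranged from 1751 to 3025, and the difference for ppa004988m at T1 to T3 was 5.51 (adjusted p = 0.059) without replicate C. The array median moved the median change by -0.28 to 0.38. Slide could not be a fixed block for flower against T1, the mesocarp time course, mesocarp T3 to T5 or the tissue difference T3 to T5. For the last 3 it entered only as a random block. Averaging probes of a gene and the gene lists were not run, since each model has 1 probe and the lists were void. Dim gene models limit the fold changes, because a level near background does not measure the gene model. Relative to the 75th percentile such a level also shifts with that percentile, which averaged 3040 in seed T1 and 795 in seed T10.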

Other observations

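The tests on flower and on alternating gene models were chosen after related values had been seen, and the bounds for the test on the return of fallen gene models were revised once after group values had been seen. The gene model ppa008837m fell, rose and fell again in mesocarp over T3, T5, T7 and T10, and did the same in seed, with a smaller amplitude. In mesocarp 196 gene models made this sequence of 3 changes and 162 the reverse one, and in seed 103 and 28. Both tissues shared 13 of the first kind and 7 of the second, where independent lists would share 0.974 and 0.219, ratios of 13.3 and 32.0. Gene models that alternated in opposite phase in the tissues numbered 7 and 0, against 0.805 and 0.265. A condition of the collection day that reached both tissues, such as the hour of sampling, is a candidate explanation for the shared phase. The lower ratio of 13.3 was above the bound of 3 set for it, but that bound cannot decide. Single steps were already shared above independent lists, by ratios of 3.66 for falls at T3 to T5, 3.69 for rises at T5 to T7 and 1.97 for falls at T7 to T10. The labels give no hour, a development common to both tissues would give the same values, and the opposite phase was also above the independent number for 1 of the sequences. Mesocarp T5, T7 and 2 of the T10 arrays lie on 1 slide, but mesocarp T3 to T5 and seed T7 to T10 lie between slides, so slide was not tested for the whole sequence.

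Gene models that fell in seed from T7 to T10 and rose from T10 to T11 were counted with the T10 arrays split so that no array served both steps. This left 1 T10 array in the later step, assumed to vary like the other groups. The 3 ways of splitting gave 618, 710 and 712 such gene models against 252, 276 and 279 for independent lists, a lowest ratio of 2.45, while those that rose at both steps lay below the independent number, at 0.676 to 0.805 of it. A return of gene models that had fallen may be part of the last seed step, but the ratios do not decide it. No other pair of successive steps was counted in this way for comparison, and a gene model near background at T10 can only stay or rise. The T11 arrays disagree, and a part played by mesocarp RNA remains open, so the return stays a hypothesis.

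Gene models that rose in mesocarp at the onset of ripening were more often higher in flower than in mesocarp T1, 872 against 383 for independent lists, a ratio of 2.27, and less often lower in flower, 243 against 348. The correlation of the changes across gene models was 0.167, under the bound of 0.2 set for a shared set, so the test decided nothing. Flower is alone on its slide.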
